A study of Apis mellifera with 3 samples.

How the data were processed

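Messenger RNA recorded as coming from hypopharyngeal glands was enriched with oligo-dT beads and fragmented, per the labels' protocols. It was made into cDNA libraries with PCR and sequenced on an Illumina HiSeq instrument. Each of the 3 samples (winter bee, spring bee, retired bee) was 1 library from 30 pooled full-sister bees. The authors deposited 1 table per library. Per the file headers, each table gives for a transcript sequence its length, the count of uniquely mapped reads, the fraction of its length covered by reads (coverage), RPKM and the best protein match with an orthology entry. The deposited RPKM equal the deposited read counts divided by sequence length in kilobases and by the library total, in the usual RPKM scale, which was checked for every sequence. The deposited read counts sum to the library total in the header. The aligner, the counting tool, their versions and the release of the sequence set are not given in the sources used here. Sequences with 0 reads are not listed, and the lowest listed value is 1 read.

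The 3 tables were joined on the sequence identifier into 21441 sequences, of which 18352 were read in all libraries. A value not listed was taken as 0. A protein match was given for 12437 sequences, on 9844 distinct proteins. Gene symbols came from the match's protein identifier in a gene table of assembly Amel_HAv3.1, which gave a symbol to 4887 sequences. That table served for names only. The matches are to proteins of several insects, so a name says what a sequence resembles. Since only uniquely mapped reads were counted, reads matching several near-identical sequences, such as those of the royal jelly protein family, are not in the counts. For royal jelly proteins and honey-processing enzymes, reads were also summed over all sequences with the same best match. These sums do not bring back reads that did not map uniquely.

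The main measure was log2 of (RPKM + 1) in 1 library over (RPKM + 1) in another, for spring over winter, retired over spring and retired over winter. This pseudocount understates the ratio of low sequences. A count of 2-fold differences took sequences with at least 10 RPKM in at least 1 of the 2 libraries. With 1 library per group no test across samples was possible and no p-values were computed across sequences. Folds of named sequences and proteins are ratios of reads per library total, each with an exact conditional binomial (Clopper-Pearson) 95% interval, and shares of reads have 95% Wilson intervals. These intervals compare libraries, not conditions. To describe how many 2-fold differences counting noise alone gives, 100 pairs of libraries with equal expected levels were drawn.

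Before the data were examined, 30 gene lists were fixed by symbol and protein description. They cover royal jelly proteins, honey-processing enzymes, secretion, translation, energy and lipid metabolism, protein turnover, cell death, stress, hormones, insulin and TOR signalling, immunity, cytochrome P450 and markers of other tissues. Because lists were matched by words and kept as fixed, some hold members outside their name, such as a transcription elongation factor among translation factors, a pyruvate dehydrogenase phosphatase among storage proteins, a cytochrome P450 reductase among cytochrome P450 and a GABA receptor-associated protein among neuron markers. A list's median log2 ratio over members with at least 10 RPKM in 1 library was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart below the 2.5th or above the 97.5th percentile. The percentile describes these libraries only, since genes are not replicates. The named sequences followed a rule also fixed before. It took the 10 highest and 10 lowest with a described match per comparison, all royal jelly and enzyme sequences with at least 10 RPKM, up to 4 members with the largest difference of each other list, and the 10 most abundant of each library.

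On simulated counts for all 21441 sequences, 99.5% of 200 planted 4-fold differences were called at least 2-fold in each comparison. Of planted 1.5-fold differences, which lie under that threshold at any depth, 4.0% were called in spring over winter, 4.5% in retired over spring and 3.0% in retired over winter. In the runs with 4-fold differences, 0.851%, 1.14% and 0.860% of the unplanted sequences were called, and the intervals held the true ratio for 95.7%, 95.5% and 95.5% of sequences. For spring over winter, lists of 25 members were simulated among 12208 sequences. They stood apart in 20 of 20 draws with a planted shift of 0.5 on the log2 scale. With no shift they stood apart in 1 of 20. Simulated counts differed only by counting noise and the planted differences. The libraries differed more, with 258 sequences at least 2-fold higher and 573 lower in spring over winter. Counting noise alone gave means of 48.7 and 51.2. The 20 of 20 and 1 of 20 therefore do not say how often a list of related genes stands apart in these libraries.

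Alternatives fixed before were pseudocounts of 0.1 and 5, minimum values of 1 and 50 RPKM or none, rescaling to a median ratio of 1 (median of ratios), rescaling after leaving out 72 royal jelly and most abundant sequences, TPM, a 4-fold threshold, list members down to 1 RPKM and lists without shared members. Added after the data were seen were a minimum of 50 reads in the 2 libraries, 1 sequence per protein, leaving out the sequences read almost only in the spring library, described sequences alone as random lists, lists that also use the orthology description, reads summed per protein, and the honey-processing enzymes without an amylase sequence that rests on 2 winter and 0 spring reads. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.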

Results

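RNA recorded as coming from hypopharyngeal glands was sequenced from 3 pools of worker honeybees of the subspecies Apis mellifera carnica, which the labels call winter, spring and retired bees. The hypopharyngeal glands lie in the head and secrete royal jelly proteins in nurse bees and sugar-processing enzymes in older bees. The series' title and design text name the regulation of gland activity and jelly secretion over winter as the question. Each pool held 30 bees and gave 1 library, so n = 1 in each group and no difference below has a replicate check. The labels give an age of 3 days after emergence to the winter pool, 6 days to the spring pool and 9 days to the retired pool. Whether these are ages of the bees or number the collections is not given in the sources used here, and winter bees commonly live for months. Season, task and labelled age therefore differed together and cannot be separated. The protocol speaks of glands and the design text of pooled heads, so whether glands or whole heads were sequenced is open. Markers of brain, eye, antenna, muscle, fat body, blood cells and cuticle were therefore followed beside the gland products. Genes of nerve cells were read in every library, with synaptotagmin 1 at 186.2, 134.1 and 143.1 RPKM and a synapsin-like sequence (TC21290) at 216.2, 180.3 and 181.6 RPKM in the winter, spring and retired libraries. In the same order bruchpilot stood at 69.84, 49.96 and 42.68 RPKM, and 43 neuron marker sequences reached at least 10 RPKM in a library. These values argue against pools of gland cells alone, so a difference below cannot be placed in gland cells.

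The winter library held 3.85 M uniquely mapped reads on 20385 transcript sequences, the spring library 3.29 M on 19772 and the retired library 3.18 M on 19574. A sequence is an assembled or single transcript entry, and several can belong to 1 gene. On a sequence of 1 kb, 3 reads corresponded to 0.780 RPKM in the winter, 0.912 in the spring and 0.944 in the retired library. Sequences with no protein match took 25.7% of the winter reads, 20.8% of the spring reads and 19.95% of the retired reads. The 10 most abundant sequences took 14.3%, 24.8% and 25.2% of the reads in the same order. The most abundant sequence of the winter library, TC20841, had no protein match and stood at 45443 RPKM there, 41982 in the spring and 41887 in the retired library. Intervals are 95% intervals from read counts. They treat reads as independent counts and leave out differences between bees and between libraries, since each group has 1 library. Reads copied by PCR are not independent molecules, so the intervals can be too narrow even for counting error. The 3 comparisons use the same 3 libraries in pairs, so opposite directions in consecutive comparisons come partly from the shared spring library.

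Spring bees against winter bees compares the pools labelled spring and winter. Royal jelly proteins, the main secreted products of nurse glands, took 21.2% of the spring reads (Wilson interval 21.12 to 21.21%) and 7.03% of the winter reads (7.01 to 7.06%). Their share was 3.01-fold higher in the spring library (exact interval 3.00 to 3.02). The enzymes that act on nectar and honey sugars went the other way, with 2.97% of the winter reads (2.96 to 2.99%) and 1.24% of the spring reads (1.23 to 1.25%). Most sequences for protein folding and translocation in the endoplasmic reticulum were higher in the spring library, and most cytosolic heat shock sequences were lower.

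**Figure D1:**
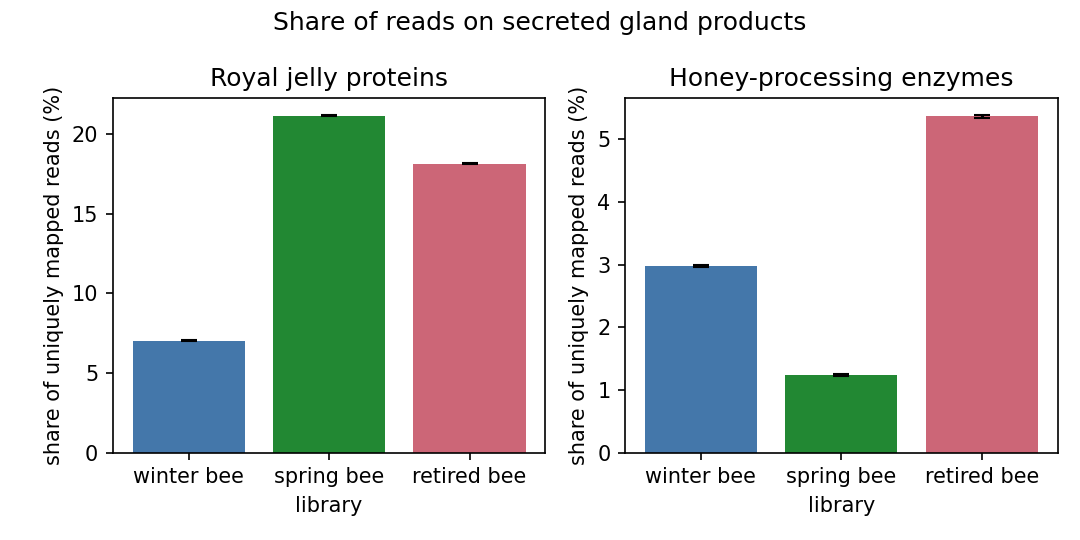
Share of uniquely mapped reads in percent (vertical axes, from 0) on the royal jelly protein list (left) and the honey-processing enzyme list (right) in the 3 libraries, 1 library per bar, with 95% Wilson intervals. Royal jelly proteins took 7.03%, 21.2% and 18.1% of the reads in the winter, spring and retired libraries, and the enzymes 2.97%, 1.24% and 5.37%.

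With reads summed over all sequences of 1 protein, Mrjp2 was 5.04-fold higher in the spring library (4.999 to 5.08) and took 9.93% of its reads, against 1.97% in winter. Mrjp7 was 3.01-fold higher (2.95 to 3.07). Mrjp1 and Mrjp4 were both 2.30-fold higher, and Mrjp5 was 2.15-fold higher. Mrjp3 was 2.34-fold higher on only 86 against 43 reads, with a wide interval (1.605 to 3.46). Mrjp6 was 3.38-fold lower in the spring library (3.25 to 3.52), and apisimin, a small jelly protein, was 1.19-fold lower (1.09 to 1.30). The 2 rescalings moved the median log2 ratio of all sequences from -0.26 to -0.01 and -0.05. The apisimin difference is about the size of that move, so it hangs on the scaling. Of the 37 royal jelly sequences with at least 10 RPKM in 1 library, 22 were at least 2-fold higher and 1, Mrjp6, was at least 2-fold lower. These 37 match only 14 proteins, so they are not independent members. The intervals of 24 lay above 1, those of 5 below 1, and 8 included 1. Over all 12038 sequences with at least 10 RPKM in 1 of the libraries, 891 intervals lay above 1 and 4098 below. Interval counts of every list in spring over winter are to be read against these. Reads that match several near-identical Mrjp sequences are not among the uniquely mapped reads. The most read Mrjp1 sequence was covered over a fraction of 0.187 of its length in the spring library and the most read Mrjp2 sequence over 0.437. Levels of single sequences are therefore uncertain. Sums per protein and the share of royal jelly reads leave out the same reads, so they are uncertain too.

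Among the enzymes, alpha-amylase was 27.3-fold lower in the spring library (23.3 to 32.2), with 158 reads against 5056. Hbg3, an alpha-glucosidase that splits sucrose, was 7.98-fold lower (7.79 to 8.18) over its 4 sequences. Glucose oxidase, which makes gluconic acid and hydrogen peroxide in honey, differed by little and was 1.03-fold lower (1.02 to 1.05). The 2 rescalings raised ratios of spring over winter by more than this difference, so its direction hangs on the scaling. Of the 10 sequences of this list, which match only 6 proteins, 5 were at least 2-fold lower. Among these 5 was a further amylase sequence with 2 winter reads and 0 spring reads. The list also took in a lysosomal alpha-glucosidase (1.21-fold lower, 0.954 to 1.55) and neutral alpha-glucosidase AB, a glycan-trimming enzyme of the endoplasmic reticulum, which was 1.61-fold higher (1.46 to 1.78).

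**Figure D2:**
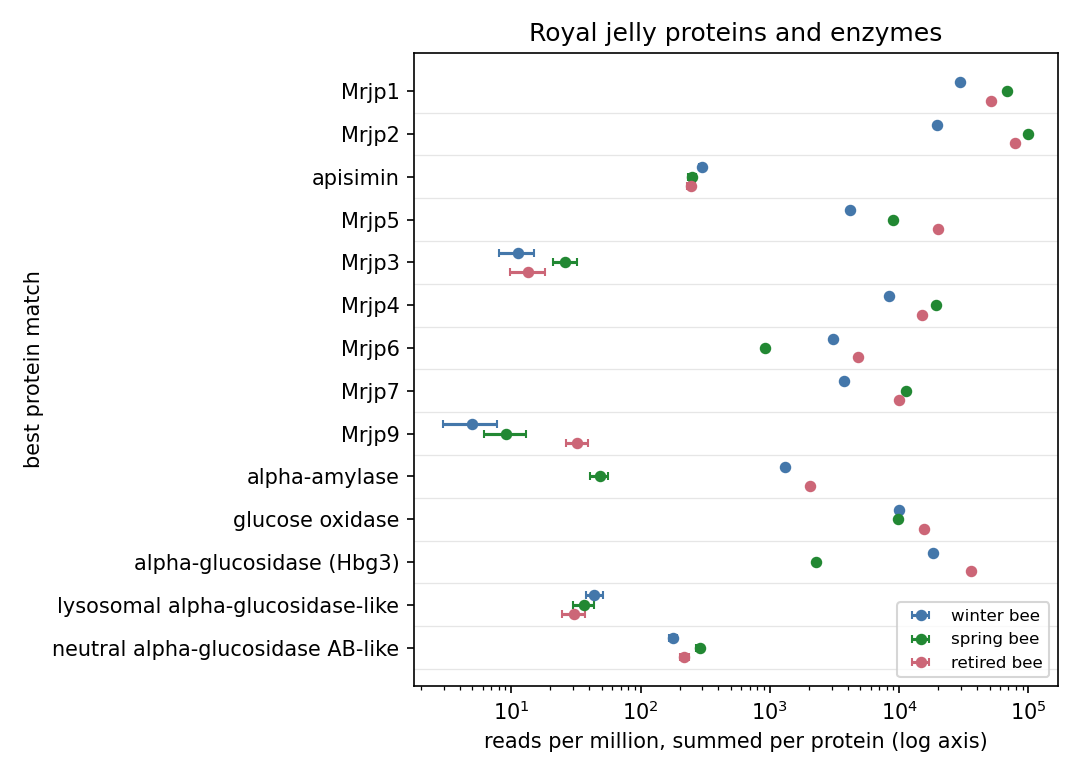
Reads scaled to a common library total (RPM, horizontal log axis), summed over all sequences with the same best protein match, in the 3 libraries (colours), with exact 95% binomial intervals that are mostly hidden by the points. Hbg3 stood at 18175, 2277 and 35925 RPM in the winter, spring and retired libraries, while Mrjp2 stood at 19713, 99328 and 78085.

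Of 49 sequences for protein processing in the endoplasmic reticulum, 16 were at least 2-fold higher in the spring library and 0 at least 2-fold lower. The intervals of 38 lay above 1, and that of 1 below. The median log2 ratio was 0.74, which is 1.01 above that of random lists matched on expression. The study's own design text names this pathway as found on these samples, so the list is not independent evidence of its direction. The translocon-associated protein subunit alpha (TC13695) was 8.46-fold higher (6.46 to 11.25). Sec61 alpha (TC12619), the channel through which secreted proteins enter the reticulum, was 3.94-fold higher (3.50 to 4.44), and Sec61 beta 3.65-fold higher (2.91 to 4.61). The chaperone Hsc70-3 was 2.81-fold higher (2.62 to 3.03). Signal peptide recognition and cleavage had 7 of 11 intervals above 1 and 0 below, with the signal peptidase subunit SEC11C 2.68-fold higher (2.23 to 3.24). Aminoacyl-tRNA synthetases, which load amino acids onto tRNA, had 17 of 21 intervals above 1 and 1 below, with seryl-tRNA synthetase 2.65-fold higher (2.05 to 3.44). Translation factors, a list that also took in 1 transcription factor (NP9548154), had 27 of 51 intervals above 1 and 7 below, with elongation factor 1-beta 1.92-fold higher (1.65 to 2.23).

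All of these lists, and those of Golgi transport, oxidative phosphorylation, the tricarboxylic acid cycle, fatty acid breakdown and the proteasome, had medians above the central 95% of 10000 matched random lists in spring over winter. The list medians of the last 5 groups were small, at 0.08, 0.11, 0.08, 0.19 and 0.14 on the log2 scale, against about -0.26 for matched lists. Matched lists also drew sequences with no protein match, whose median was -0.37, against -0.20 for described ones. A list of described sequences thus starts above them. These lists kept their place under all 10 alternatives, 1 of which drew random lists from described sequences alone. Cytosolic ribosomal proteins had a median of -0.12, above that of matched lists, with 12 of 77 intervals above 1 and 36 below. That median became 0.12 after rescaling to a median ratio of 1, and the list no longer stood apart (89.00th percentile) against described sequences alone. Cytosolic heat shock proteins (-0.55) stood below matched lists, under 9 of 10 alternatives as well. Of 22 heat shock sequences, 14 had intervals below 1 and 2 above, and the small heat shock protein TC12617 was 2.63-fold lower (2.455 to 2.81). Honey-processing enzymes (median -0.63) also lay below, but this place hung on the amylase sequence with 2 reads. Without it the median was -0.26, at the 42.2nd percentile, so the list as a whole did not stand apart, and the difference rests on alpha-amylase and Hbg3.

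The other lists did not stand apart in spring over winter. Their medians were -0.18 for glycolysis, -0.32 for fatty acid synthesis, -0.24 for trehalose and sugar transport, -0.21 for lysosome and autophagy, -0.28 for cell death and -0.23 for antioxidant enzymes. They were -0.43 for the juvenile hormone and ecdysteroid pathway, -0.36 for insulin and TOR signalling, -0.32 for immune effectors and -0.32 for cytochrome P450. Markers of other tissues had medians of -0.36 for neurons, -0.37 for photoreceptors, -0.39 for muscle, -0.40 for fat body storage proteins, -0.41 for hemocytes, -0.42 for antenna and -0.22 for cuticle. The neuron markers lay at the 5.145th percentile of matched lists and the muscle markers at the 21.0th. Under 1 alternative each the neuron markers, the juvenile hormone and ecdysteroid pathway and the immune effectors stood below matched lists, and under 3 the muscle markers did.

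Among single sequences with a named match, glucose dehydrogenase (TC14055) was 41.2-fold higher in the spring library (34.1 to 50.3), with 3875 reads against 110. A takeout-like protein (TC13883) was 17.5-fold higher (11.5 to 27.99), asparagine synthetase 12.5-fold higher (10.4 to 15.2) and a glucosylceramidase-like enzyme 10.8-fold higher (8.67 to 13.7). Of the 10 highest, 3 matched an RNA-dependent RNA polymerase entry from a spider and were read almost only in this library. A phosphate cotransporter (NP9549518) was 9.89-fold lower (6.19 to 16.75), the chemosensory protein CSP1 7.32-fold lower (6.725 to 7.975) and vitellogenin, the yolk and storage protein of long-lived bees, 5.35-fold lower (4.55 to 6.32). The lipid carrier A4, like apolipophorin-III and also of the fat body list, was 2.34-fold higher (1.70 to 3.26). Over all 12038 sequences with at least 10 RPKM in 1 of the libraries, 258 were at least 2-fold higher and 573 at least 2-fold lower in the spring library. Counting noise alone gave means of 48.7 and 51.2 in simulated pairs of equal libraries. The median log2 ratio was -0.26, so more sequences lay on the winter side. After rescaling to a median ratio of 1 the split was 419 higher and 255 lower, and after rescaling without royal jelly proteins and the most abundant sequences it was 456 and 396.

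**Figure D3:**
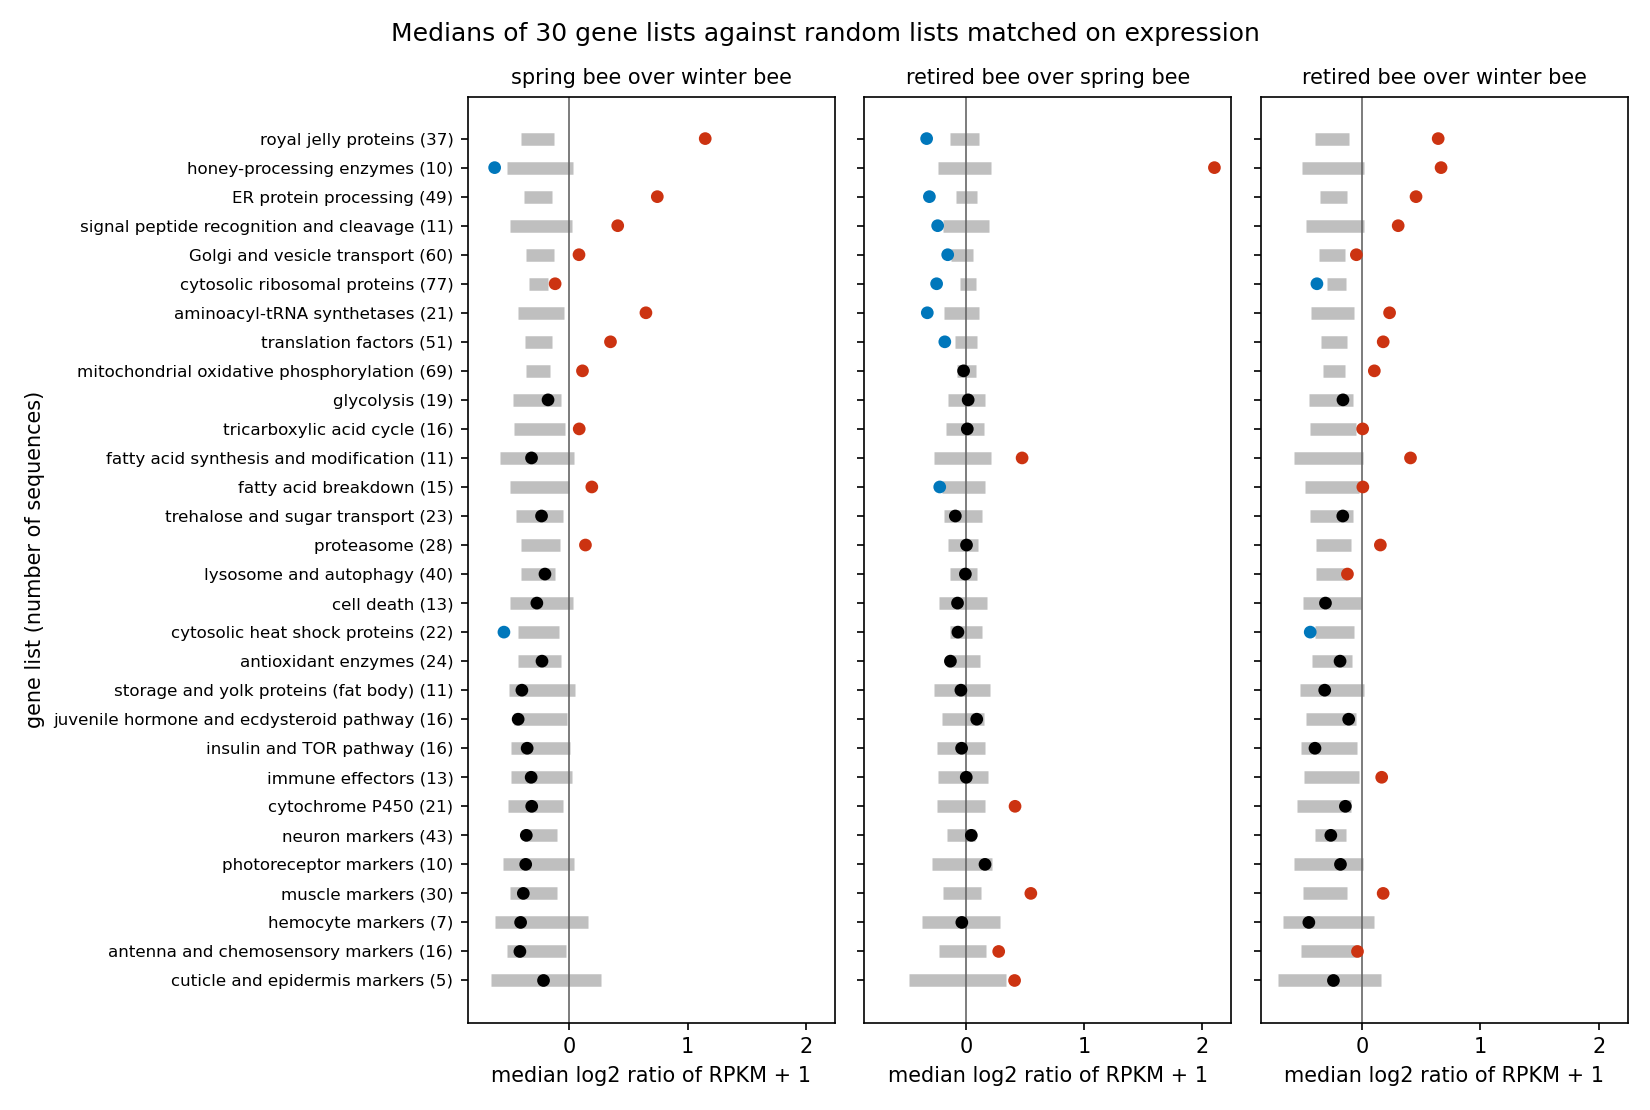
Median log2 ratio of RPKM + 1 (horizontal axes) of 30 gene lists (rows, with the number of sequences) in the 3 comparisons (panels). Grey bars span the central 95% of 10000 matched random lists, red points lie above and blue points below them, and black points do not stand apart. Royal jelly proteins stood at 1.15, -0.33 and 0.64 and honey-processing enzymes at -0.63, 2.10 and 0.67 from left to right.

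Retired bees against spring bees compares the pools labelled retired and spring. Honey-processing enzymes took 5.37% of the retired reads (5.34 to 5.39%), a share 4.34-fold higher than in the spring library (4.29 to 4.385). Royal jelly proteins kept a high share of 18.1% (18.10 to 18.18%), which was 1.17-fold lower than in the spring library (1.16 to 1.17). Most sequences of endoplasmic reticulum processing, aminoacyl-tRNA synthetases and ribosomal proteins were lower in the retired library. Fatty acid synthesis was higher for 6 of 11 sequences and muscle markers for 13 of 30.

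Alpha-amylase was 42.4-fold higher in the retired library (36.2 to 49.98), Hbg3 15.8-fold higher (15.4 to 16.15) and glucose oxidase 1.59-fold higher (1.57 to 1.61). Of the 10 enzyme sequences, which match only 6 proteins, 8 had intervals above 1 and 1 below. Over all 11413 sequences with at least 10 RPKM in 1 of the libraries, 994 intervals lay above 1 and 1251 below. The median log2 ratio of the enzyme list, 2.10, became 0.68 without the low amylase sequence and still stood above matched lists. The royal jelly proteins split. Mrjp1 was 1.33-fold lower, Mrjp2 1.27-fold lower, Mrjp4 1.275-fold lower and Mrjp7 1.135-fold lower in the retired library. Mrjp3 was 1.93-fold lower (1.325 to 2.86), and sequences matching another Mrjp3 entry and an unnumbered royal jelly protein entry were 1.955-fold and 1.835-fold lower in sum. The sum of the unnumbered entry joined sequences that went opposite ways. TC12751 was 2.77-fold higher (2.51 to 3.07) and TC18087 was 2.38-fold lower (2.29 to 2.47). The interval of apisimin included 1 (0.895 to 1.09). Mrjp5 was 2.24-fold higher (2.21 to 2.27), Mrjp6 5.24-fold higher (5.04 to 5.45) and Mrjp9, with 103 reads against 30, 3.55-fold higher (2.35 to 5.53). In all, 20 of 37 royal jelly intervals lay below 1, 4 above and 13 included 1.

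Of 49 sequences for processing in the endoplasmic reticulum, 30 had intervals below 1 and 2 above, with a median log2 ratio of -0.31. The translocon-associated subunit TC13695 was 2.77-fold lower (2.30 to 3.35) and Sec61 alpha 2.07-fold lower (1.87 to 2.29). Aminoacyl-tRNA synthetases (median -0.33, 12 of 21 intervals below 1), translation factors (-0.18, 19 of 51), cytosolic ribosomal proteins (-0.25, 48 of 77), signal peptide handling (-0.24, 4 of 11), Golgi transport (-0.15, 12 of 60) and fatty acid breakdown (-0.22, 5 of 15) also stood below matched lists. Fatty acid breakdown lost this under 1 of 10 alternatives, at the 3.23rd percentile.

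Fatty acid synthesis and modification stood above matched lists (median 0.48), with 6 of 11 intervals above 1 and 1 below. Fatty acyl-CoA reductase FAR1, which makes fatty alcohols, was 4.97-fold higher in the retired library (4.385 to 5.65). Acetyl-CoA carboxylase, which starts fatty acid synthesis, was 3.11-fold higher (2.73 to 3.54), and an elongase (TC14076) was 5.37-fold higher (3.345 to 9.03). Cytochrome P450 had a median of 0.42, with 8 of 21 intervals above 1 and 0 below. It stood above matched lists under 9 of 10 alternatives but lay at the 79.9th percentile after rescaling without royal jelly proteins and the most abundant sequences. Muscle markers moved with these groups, with a median of 0.55 and 13 of 30 intervals above 1. Troponin C type IIIa was 3.14-fold higher in the retired library (2.63 to 3.78). Antenna markers (0.28, 5 of 16 intervals above 1) and cuticle markers (0.41, 2 of 5) also stood above matched lists. The eye opsin Lop1 was 9.94-fold higher (7.57 to 13.3), while the photoreceptor list lay at the 93.8th percentile and stood above matched lists under 4 alternatives. Of its 10 sequences, 3 had intervals above 1 and 1 below. An arrestin homolog (TC14219) was 4.63-fold higher (2.79 to 8.065), and a rhodopsin-like sequence (NP9547279) was 3.26-fold lower (1.44 to 8.31).

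The remaining lists did not stand apart in retired over spring, with medians from -0.13 for antioxidant enzymes to 0.16 for photoreceptors. Neuron markers had a median of 0.05 and stood above matched lists under 1 alternative. Over all 11413 sequences, 207 were at least 2-fold higher and 224 at least 2-fold lower in the retired library, where counting noise alone gave means of 61.65 and 60.5. The median log2 ratio was -0.02. The 4-read spring level of a venom acid phosphatase (TC14476) made its 68.6-fold higher ratio wide (26.5 to 253.5), and a pancreatic lipase-like sequence was 18.6-fold higher (7.69 to 58.8) on 90 against 5 reads. Among sequences with a described match, the 3 lowest in the retired library were the polymerase matches, and among the next an alcohol dehydrogenase (TC21661) was 3.865-fold lower (2.495 to 6.19).

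Retired bees against winter bees compares the pools on either side of the spring pool. Both product groups were higher in the retired library, with royal jelly proteins 2.58-fold higher (2.57 to 2.59) and honey-processing enzymes 1.805-fold higher (1.79 to 1.82) as shares of reads. Most sequences of endoplasmic reticulum processing were higher, and most ribosomal and cytosolic heat shock sequences were lower. Of the fat body proteins, vitellogenin and hexamerin were lower and A4 was higher.

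Mrjp5 was 4.80-fold higher in the retired library (4.72 to 4.89), Mrjp2 3.96-fold higher (3.93 to 3.99), Mrjp7 2.65-fold higher (2.60 to 2.70) and Mrjp6 1.55-fold higher (1.51 to 1.59). Mrjp9 was 6.57-fold higher (3.999 to 11.35) on 103 against 19 reads. Apisimin was 1.205-fold lower (1.10 to 1.32), and the interval of Mrjp3 included 1 (0.775 to 1.89). The 2 rescalings moved the median log2 ratio of all sequences from -0.26 to -0.009 and -0.05. The apisimin difference is about the size of that move, so it hangs on the scaling. Hbg3 was 1.98-fold higher (1.96 to 1.995), alpha-amylase 1.55-fold higher (1.495 to 1.61) and glucose oxidase 1.54-fold higher (1.52 to 1.56). Among the royal jelly sequences, 20 of 37 intervals lay above 1 and 4 below, and among the enzymes 8 of 10 lay above 1 and 1 below. Over all 11955 sequences with at least 10 RPKM in 1 of the libraries, 675 intervals lay above 1 and 4036 below. Interval counts of every list in retired over winter are to be read against these.

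For processing in the endoplasmic reticulum, 30 of 49 intervals lay above 1 and 2 below, with a median of 0.46. The translocon-associated subunit TC13695 was 3.06-fold higher (2.26 to 4.18), Hsc70-3 2.64-fold higher (2.45 to 2.84) and endoplasmin 2.33-fold higher (2.11 to 2.58). Signal peptide handling (0.30), aminoacyl-tRNA synthetases (0.23), translation factors (0.18), oxidative phosphorylation (0.10), the proteasome (0.15), fatty acid synthesis (0.41) and muscle markers (0.18) also stood above matched lists. Fatty acid synthesis turned to -0.06 when members down to 1 RPKM were counted, and then no longer stood apart (97.14th percentile). Golgi transport (-0.05), the tricarboxylic acid cycle (0.004), fatty acid breakdown (0.005), lysosome and autophagy (-0.125), antenna markers (-0.04) and immune effectors (0.16) stood above matched lists as well, and each of these 6 medians took the other sign under at least 1 alternative. Fatty acid breakdown and lysosome stood apart under only 5 of 10 alternatives each, antenna markers under 7, and the tricarboxylic acid cycle and immune effectors under 9 each. In all, 16 lists stood above matched lists in retired over winter. Here too the median of described sequences (-0.21) was above that of undescribed ones (-0.37), which random lists also drew.

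Cytosolic ribosomal proteins stood below matched lists (median -0.38), with 51 of 77 intervals below 1 and 3 above. Cytosolic heat shock proteins also stood below (-0.44, 14 of 22 intervals below 1), under 8 of 10 alternatives. The small heat shock protein TC14876, with 28738 winter reads, was 2.56-fold lower in the retired library (2.501 to 2.62). Vitellogenin was 5.52-fold lower (4.68 to 6.56) and hexamerin (TC12320) 5.33-fold lower (3.68 to 7.94), A4 was 4.04-fold higher (3.01 to 5.51), and the fat body list as a whole lay at the 30.0th percentile. With members down to 1 RPKM the fat body list, storage and yolk proteins with 1 pyruvate dehydrogenase phosphatase (TC12840) that does not belong to them, stood below matched lists (median -0.67, 0.24th percentile). Glucose dehydrogenase was 29.5-fold higher (24.4 to 36.0), a sequence like an ecdysteroid glucosyltransferase (TC16552) 22.15-fold higher (10.4 to 56.2) and the cytochrome P450 TC14206 8.63-fold higher (6.64 to 11.36). The other lists did not stand apart, with medians from -0.45 for hemocyte markers to -0.11 for the juvenile hormone and ecdysteroid pathway, and neuron markers at -0.27. Cytochrome P450 (-0.14) stood above matched lists under 2 alternatives and turned to 0.23 after rescaling to a median ratio of 1. Over all 11955 sequences, 157 were at least 2-fold higher and 649 at least 2-fold lower in the retired library, where counting noise alone gave means of 51.7 and 52.9. After rescaling to a median ratio of 1 these became 293 and 294, and after rescaling without the most abundant sequences 330 and 455.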

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

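For the low median ratio, the bounds of the tests on depth and on royal jelly transcripts were written after the median had been seen but before the test values were computed. All other tests in this part were chosen after the results were seen. For depth, for brain tissue, for gland tissue, for bee genes and for an immune response, the written outcome against the explanation was set aside after the values were seen, for the reasons given beside them.

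A group of 15 sequences, with at least 50 spring reads and at most 2 reads in each other library, took 38762 spring reads, or 1.18% of the library (1.17 to 1.19%), and the same rule gave 0 sequences in the winter and 0 in the retired library. Best matches were an RNA-dependent RNA polymerase entry from the spider Latrodectus hesperus for 3 and none for 12, so RNA from a virus in the spring bees is a possible source that was not tested on virus sequences. Bee genes active only in the spring pool could not be told. Of the 15, 0 had a bee protein match (exact upper limit 21.80%). The written comparison, 2781 other sequences of as high a level, had 47.82% with such a match. Among 1448 of these of the same lengths it was 23.4%. The limit rises to 84.2% if the 15 are pieces of only 2 RNAs. Carry-over from a library outside the series could not be told, since reads covered a median fraction of 0.9205 of the sequences and coverage alone does not exclude it. An immune response could not be told either, since immune effectors lay at the 30.00th percentile of matched lists with 3 intervals above 1 and 6 below, and at the 1.17th with members down to 1 RPKM, and a median misses a response carried by a few members.

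More sequences were lower than higher in the spring than in the winter library, with a median log2 ratio of -0.26. With the winter reads thinned to the retired depth the median was -0.2600, but RPKM already divide by the library total, so thinning could hardly move it and says nothing on the depth of the winter library. Royal jelly proteins took 7.03% of the winter and 21.2% of the spring reads. This leaves a smaller share for all other sequences and lowers their RPKM by construction, so it may account for much of the shift. Rescaling without royal jelly and the most abundant sequences moved the median to -0.05385, between the written bounds. That rescaling also left out abundant sequences of other kinds, so it cannot say how much is due to royal jelly alone. Less brain tissue in the spring pool could not be told, since neuron markers lay at the 5.145th percentile of matched lists, outside the bound written for it, but at the 0.46th against described sequences alone. The difference of season and task between the pools was not tested.

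Alpha-amylase and Hbg3 were low in the spring library while royal jelly proteins were high. For Hbg3, on which alone these tests were run, a larger royal jelly share was argued against as the whole cause. Rescaling changes all ratios between libraries by a common factor, so it could hardly have removed so large a fold. The main Hbg3 sequence was still 6.951-fold lower after it, which shows only that this share accounts for little of the difference. Reads moving among the Hbg3 sequences would leave their sum unchanged, and the sum was 7.983-fold lower. The main sequence held 68385 of 69938 winter and 7282 of 7486 spring Hbg3 reads, so summing could hardly change the fold. Reads that did not map uniquely, or that fell on sequences with another best match, are not in this sum and were not tested. Less gland tissue in the spring pool could not be told. Royal jelly transcripts were 3.009-fold higher there, but they are themselves a gland product compared here. A higher level per gland could hide a smaller amount of gland. A difference in gland product or in tissue between the pools may underlie the pattern. This is a hypothesis from 1 library per group that was not tested, with season, task and labelled age not separable.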

How the results depend on the processing

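Minimum reads, 1 sequence per protein, leaving out the spring-only sequences or a low amylase sequence, described or orthology-extended lists and sums per protein were chosen after seeing the data, and the other settings before. Counts of 2-fold differences depended on the settings, given here as higher and lower for spring over winter, retired over spring and retired over winter. With a pseudocount of 5 they were 291 lower, 110 and 104, and 104 and 301. At 1 RPKM, or with no filter, they were 708 and 1663, 865 and 1150, and 528 and 1980. At 50 RPKM they were 119 and 155, 49 and 32, and 63 and 123. After median-of-ratios rescaling they were 419 and 255 in the first and 293 and 294 in the last comparison. After rescaling without royal jelly and abundant sequences they were 456 higher, 338 lower and 330 higher. At 4-fold they were 61 and 49, 32 and 23, and 44 and 41. With at least 50 reads they were 352 lower, 113 and 76, and 347 lower. With 1 sequence per protein they were 138 and 185, 98 and 57, and 89 and 162. Fewer or more sequences tested, or a stricter fold, changes the counts by construction. For both rescalings the median shift moves the counts against winter, but the rescaling without abundant sequences also tested more sequences, 12809 against 11413 in retired over spring, where the median hardly moved and higher and lower counts both grew. Other counts, 26 in number, stayed within 1.5 times, among them all under TPM, a pseudocount of 0.1 and without the spring-only sequences. The medians of royal jelly proteins and of endoplasmic reticulum processing stood apart on the same side in all 3 comparisons under every alternative run. Honey-processing enzymes did so against spring and winter bees for the retired library. In spring over winter their median was -0.24 with a pseudocount of 5 (53.69th percentile), -0.54 with members down to 1 RPKM, -0.63 with 1 sequence per protein and -0.49 with orthology descriptions, the last 3 between the 2.82nd and 2.90th percentile. Without the amylase sequence DB772014, with 2 winter and 0 spring reads, it was -0.26 (42.2nd percentile), so the main place apart and its loss with a pseudocount of 5 hang on that sequence. The cause of the other 3 was not tested. Of the list medians under alternatives, 808 kept direction and side, 22 lost and 14 gained their place apart, 43 of lists not apart changed sign and 16 changed sign. In retired bee over winter bee, Golgi and vesicle transport turned to 0.19 (median of ratios), 0.16 (rescaled without abundant sequences) and 0.00548 (TPM), lysosome to 0.12 and 0.11 under the same rescalings, and antenna and chemosensory markers to 0.30, 0.17, 0.0169 (TPM) and 0.0612 (orthology). Ribosomal proteins in spring over winter turned to 0.12 and 0.0863 under both rescalings. These follow the median shift, apart from the orthology value. In retired over winter, orthology descriptions turned the tricarboxylic acid cycle to -0.00296 and fatty acid breakdown to -0.11, and members down to 1 RPKM turned fatty acid synthesis to -0.0583, fatty acid breakdown to -0.18 and immune effectors to -0.15; the cause was not tested. Of the folds of named sequences under alternatives, 2810 were scored as the same, 381 as moved and 4 as reversed. Among the moved, 121 came under median of ratios and 108 under rescaling without abundant sequences. Summed per protein, the apisimin sequence TC22389 turned to -0.25 and the ribosomal L35a sequence DB733754 to -0.29 (spring over winter), the royal jelly sequence TC12751 to -0.88 (retired over spring) and the Mrjp1 sequence DB743511 to 0.79 (retired over winter), since other sequences of the same protein hold more reads. For TC12751 the sum does not correct its own ratio, which rests on 1402 retired and 523 spring reads. The pathway-assignment alternative was not run, because the tables carry orthology entries and no pathways. No paired analysis was possible because each group has 1 library. Depth limits low sequences: 3 reads on 1 kb stand for up to 0.944 RPKM.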

Other observations

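Immune products did not go one way. Defensin-1 had 11323 reads in the winter, 5151 in the spring and 12835 in the retired library, and was 2.58-fold higher in retired than in spring bees (2.496 to 2.66). Abaecin, another antimicrobial peptide, followed the same order and was 2.82-fold lower in the spring than in the winter library (1.75 to 4.72). Hymenoptaecin was 6.58-fold higher in the spring than in the winter library (3.07 to 16.2) on 45 against 8 reads. Phenoloxidase, which acts in melanisation, was 2.35-fold lower in the spring library (1.86 to 3.00) and 2.345-fold lower in the retired library (1.85 to 3.00) than in winter. Lysozyme c-1 was 2.87-fold higher in spring than in winter bees (1.97 to 4.25).

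Members of the fatty acid synthesis list went different ways, and in spring over winter the list did not stand apart (43.7th percentile), with 2 of 11 sequences at least 2-fold higher and 3 lower. FAR1 stood at 85.9 RPKM in the winter, 36.4 in the spring and 181.2 in the retired library, acetyl-CoA carboxylase at 31.3, 13.5 and 41.9, and a fatty acid synthase-like sequence (TC14567) at 137.9, 59.2 and 119.0. The elongase TC16109 was lowest in the winter library, at 1.65, 8.13 and 11.6 RPKM. Sequences matching venom acid phosphatase went opposite ways. TC15604 had 233, 2009 and 1216 reads and TC14476 had 64, 4 and 265 in the winter, spring and retired libraries. The lysosomal alpha-mannosidase TC13073 was 4.63-fold higher in the spring than in the winter library (4.23 to 5.08), and the gustatory receptor Gr10 was 8.53-fold higher (5.73 to 13.15). Kr-h1, a factor of juvenile hormone signalling, was 2.68-fold higher in the retired than in the spring library (1.78 to 4.105). These sequences were named by the rule fixed before, and their orders across libraries have no replicate check.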
